A study of Homo sapiens with 30 samples.

How the data were processed

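The study measured RNA, coding and noncoding, in primary normal human lung fibroblasts by bulk RNA sequencing. Per the labels' protocols, cells were serum-starved overnight, pre-incubated for 60 min with an inhibitor or its vehicle (vehicle A, DMSO), and then given TGF-β at 2 ng/ml or its vehicle (vehicle B) for 24 h. The inhibitors were saracatinib at 0.3 µM, nintedanib at 1 µM and pirfenidone at 20 µg/ml. Total RNA was depleted of ribosomal RNA, made into stranded libraries with the KAPA kit and sequenced as paired reads on a NovaSeq instrument. Samples were grouped by the treatments in their labels, which gave 10 groups of 3 libraries and 30 libraries in all.

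The authors deposited a table of raw counts per gene, which holds 58735 Ensembl genes, and a table of log2 values. Per the submitters' processing notes, the tools named were Trim Galore, FastQC, STAR 2.6.1d, Subread featureCounts 1.6.3, Picard 2.18.21 and limma, with hg38 as the genome build. The annotation release, the strand setting and the role of each tool were not stated, so counts of antisense and overlapping genes are uncertain. The deposited log2 values cover 39200 genes, which are those with at least 1 count. They equal the log2 of CPM over the library total with an offset added to each count, and the largest difference from that recomputation was 5.0e-09. No other scaling was found in them. Gene symbols, types and positions (GRCh38) came from GENCODE 29, in which 58735 of the identifiers were found. The current symbol table held 58207 of them.

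Total counts ran from 30.3 M to 53.8 M per library (M, mega), with a median of 43.7 M. At such a depth a gene with no count in the 3 libraries of a group can still hold up to 3 counts over the group. That floor and the 95% counting intervals (exact binomial) cover counting error only, because reads without molecular identifiers are not independent molecules. Levels are given as counts per M counts of the library (CPM) after TMM normalisation, as mean and SD over the 3 libraries of a group. The replicate numbers follow the order of submission and pair no libraries between groups. Nothing in the labels says that the 3 libraries of a group are separate cultures, so the p-values measure the spread between these libraries alone.

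The following choices were made before the data were examined, except where another time is given. Differential expression was tested with edgeR 4.0.16 (R 4.3.3) on the raw counts of all 30 libraries in 1 model with a mean per group. Genes were kept by filterByExpr (minimum count 10, minimum total 15), which left 18950 genes, and libraries were scaled by TMM. Each of the 15 contrasts was tested with the quasi-likelihood F test, two-sided, and p-values were adjusted over all genes tested by the Benjamini-Hochberg method, with 0.05 as the threshold. Fold changes are log2 values from this model and are given with a standard error computed from the fold change and its F statistic. The contrasts compared TGF-β with vehicle, each drug with its vehicle in stimulated and in unstimulated cells, the effect of each drug between stimulated and unstimulated cells (interaction), each pair of drugs in stimulated cells, and each vehicle with medium.

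Named genes were chosen by rule. Within each contrast they passed the threshold, had a mean of at least 1 CPM in the higher group, and had no overlap between the libraries of the groups compared. For the interactions the floor applied to the highest mean of the groups involved, and overlap was not checked. The 10 largest rises and the 10 largest falls by log2 fold change were taken for TGF-β and for the drugs in stimulated cells, and 5 of each for the other contrasts. Chance gives no overlap in 10% of genes with 3 libraries against 3. ACTA2, COL1A1, FN1, CCN2 and SRC are reported in every group. Results for 2 further genes that these rules name are not reported here. Genes without a proper symbol were not named, and 6 genes that were tested are not printed because their level can reveal a personal trait.

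The 30 gene lists held 478 entries for 474 genes, of which 432 entries were tested. The lists were fibrillar collagens and matrix proteins, smooth-muscle contractile genes, SMAD feedback and direct TGF-β targets, BMP and ID targets, YAP and TEAD targets, MRTF and SRF targets, epithelial-mesenchymal transition factors, and the WNT pathway. Further lists were DNA replication, mitosis, ERK pathway feedback and output, inflammatory cytokines and NF-κB targets, interferon-stimulated genes, cholesterol synthesis genes, lysosome genes, aryl hydrocarbon receptor targets, NRF2 targets, and ATF4, serine and one-carbon genes. The remaining lists were endoplasmic reticulum chaperones, hypoxia and glycolysis genes, lipofibroblast and adipogenic genes, matrix proteases and inhibitors, p53 targets and senescence, growth factors and their receptors, Src-family kinases and substrates, and markers of epithelial, endothelial, leukocyte, mesothelial and pericyte cells. Each list was tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and again with a correlation estimated from the data, and adjusted over the lists of a contrast. Up to 4 called members with the largest change are given as examples.

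A TGF-β response score was computed for each library as the summed log2 CPM deviation from the unstimulated control, signed by the direction of the TGF-β change, over the genes that passed the threshold and changed at least 2-fold. It was scaled so that the unstimulated control lies at 0 and the TGF-β group at 1. Each library of the TGF-β group was scored with itself left out of the choice of genes and of the scale. Drug libraries were scored on all 3 libraries of the TGF-β group, so the scales differ. Scores were compared by exact permutation tests, two-sided, which cannot give less than p = 0.1 with 3 libraries against 3. The slope of the TGF-β response with a drug present on the response without it was computed over the same genes from groups that share no library, with a standard error by leaving out each library in turn.

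The alternatives comprised RLE size factors, library size as the only scaling, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, limma on the deposited log2 values, models of the compared groups alone, a 2-fold minimum, other unstimulated controls, other settings of the score, and leaving out in turn each library of the groups compared. A model without 3 libraries that stood apart from their groups, which tested 19289 genes, and a model with a term for those libraries were added after the data had been seen. Drug groups that share the TGF-β group as their control were compared with 20 simulated data sets in which a drug changed nothing and libraries varied independently. The method was tested on simulated data with 1.5-fold, 2-fold and 4-fold changes set in the saracatinib group with TGF-β. The changed genes were drawn from those with a mean of at least 1 CPM, and libraries were simulated independently. The shares below therefore cover neither weaker genes nor the shift of the 3 libraries that stand apart. The main model recovered 37.3%, 71.6% and 93.9% of these genes and called 7 of 18412 unchanged genes. Without the 3 libraries it recovered 79.1%, 91% and 100%. For the interaction the shares were 16.4%, 56.7% and 86.4% with all libraries. No library was left out of the main model.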

Results

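RNA, depleted of ribosomal RNA, was measured in primary human lung fibroblasts under 10 treatments, with 3 libraries for each and 30 libraries in all. In 4 groups TGF-β, the growth factor that turns fibroblasts into matrix-producing myofibroblasts, was given after vehicle A (the TGF-β group), saracatinib, nintedanib or pirfenidone. In 4 further groups the same pretreatments were followed by vehicle B, and vehicle A followed by vehicle B served as the unstimulated control. The last groups received vehicle A in plain medium, or medium followed by vehicle B. Saracatinib inhibits Src-family kinases, nintedanib inhibits the receptors of PDGF, FGF and VEGF, and pirfenidone is an antifibrotic drug with no single known target. The series asks which transcripts each drug changes with and without TGF-β. Total counts ran from 30.3 M to 53.8 M per library, with a median of 43.7 M.

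TGF-β treatment separated the libraries along the first principal component of log2 CPM, which held 63.7% of the variance of 19190 genes. The second component held 19.9% and set 3 libraries apart: replicate 3 of vehicle A in medium, of saracatinib with TGF-β and of nintedanib with TGF-β. These 3 lay at −59.0, −60.8 and −54.8, and the other 27 at −0.7 or higher. Their mean correlation across genes with the rest of their own group was 0.981, 0.978 and 0.969, against 0.998 for every library of the 7 groups without such a library. With one another the 3 libraries correlated at 0.99 to 0.997. Against the other libraries of their groups, the median of the matrix list was −0.46, −1.78 and −1.54 (log2), and that of the DNA replication list 1.52, 1.99 and 2.50. COL3A1, a fibrillar collagen, had 599, 607 and 822 CPM against means of 2290, 4330 and 7540 CPM in the rest of the groups. RRM2, a subunit of the enzyme that makes deoxynucleotides, had 109, 97.6 and 81.3 CPM against 22.8, 15.8 and 6.04 CPM. Common dispersion was 0.0351 with the 3 libraries and 0.00303 without them, so counts from the 27 other libraries stand beside those from all 30.

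**Figure D1:**
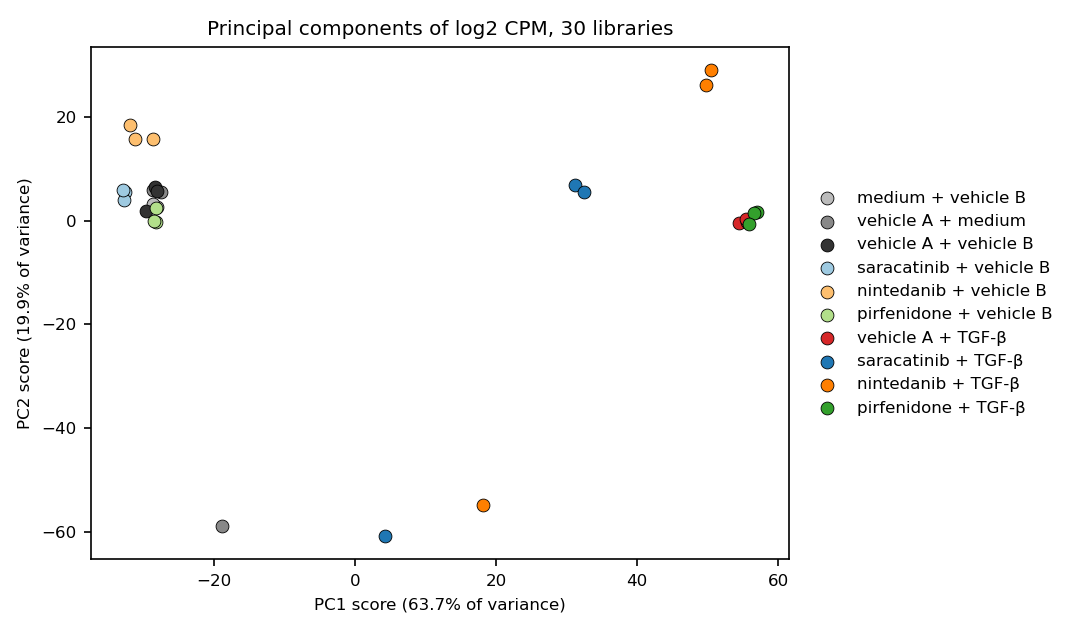
Scores of the 30 libraries on the first and second principal component of log2 CPM, with the share of variance on each axis; each point is a library, coloured by treatment. TGF-β libraries lie to the right, and 3 libraries from separate groups lie at or below −54.8 on the second component.

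TGF-β with vehicle A was compared with the unstimulated control to ask what TGF-β alone does. TGF-β raised 27 of 29 matrix genes and 15 of 17 SMAD targets, and lowered 6 of 10 lipofibroblast and adipogenic genes. COMP (ENSG00000105664, chromosome 19, 18782773 to 18791314, GRCh38), a cartilage and scar matrix glycoprotein, went from 0.05098 ± 0.0563 to 21.58 ± 2.16 CPM (SD, n = 3 each), a log2 fold change of 8.66 (SE 0.63, edgeR adjusted p = 1.7e-10). PRG4, the lubricant proteoglycan lubricin, rose from 0.1368 ± 0.0767 to 131.3 ± 12.2 CPM (log2 9.88, SE 1.14, adjusted p = 2.6e-07). ADH1B (ENSG00000196616, chromosome 4, 99304964 to 99352760), an alcohol dehydrogenase, fell from 92.8 ± 11.6 to 0.2588 ± 0.0202 CPM (log2 −8.47, SE 0.96, adjusted p = 2e-07). Of 18950 genes tested, 2985 rose and 3185 fell, 6170 in all. With library size as the only scaling, which moved the median of all genes by −0.31, the balance was 1365 raised and 6744 lowered.

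Other named rises were FOXS1, a forkhead factor (at least 429-fold higher than a control at 0, adjusted p = 2.4e-05), KANK4 (at least 288-fold), ZPLD1 (at least 182-fold) and LDLRAD4, a SMAD inhibitor (at least 87.3-fold). The floor behind these bounds is 3 counts over the group. EGR2, a zinc-finger factor, reached 31.02 ± 1.82 CPM against 0.02077 in the control, a ratio of 1440 with a counting interval of 492 to 6980. The ratio was 883 (158 to 34900) for ST6GAL2 and 540 (149 to 4470) for LINC02593. MDFI, an inhibitor of myogenic factors, rose by a log2 fold change of 8.22. The other named falls were FMO2, a lung monooxygenase (−6.37), NR4A3, an orphan nuclear receptor (−6.04), RASL11A (−5.98), LMOD3 (−5.96), KCNF1 (−5.86), IPCEF1 (−5.20), FGL2 (−4.78), SLCO4A1-AS2 (−4.73) and GUCY1A1, a subunit of the nitric oxide receptor (−4.56).

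Among the 5 genes reported in every group, TGF-β raised 4. ACTA2, smooth-muscle actin (chromosome 10, 88935074 to 88991339), rose from 24.21 ± 0.953 to 118.7 ± 11.5 CPM, with a log2 fold change of 2.29 (adjusted p = 0.0003). COL1A1 (chromosome 17, 50183289 to 50201632) rose by 2.90 (adjusted p = 1.4e-05) to 27040 ± 401 CPM, and FN1, fibronectin (chromosome 2, 215360440 to 215436172), by 1.96 (adjusted p = 0.00016) to 98360 ± 1610 CPM. CCN2, connective tissue growth factor (chromosome 6, 131948176 to 131951373), rose by 2.64 (adjusted p = 2.7e-10). SRC (chromosome 20, 37344685 to 37406050), the kinase that saracatinib inhibits, had 39.18 against 37.9 CPM (log2 0.05, adjusted p = 0.79). With library size as the only scaling, and in the deposited log2 values, the value for SRC was −0.26 and passed the threshold. Changes are therefore given relative to most genes.

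**Figure D2:**
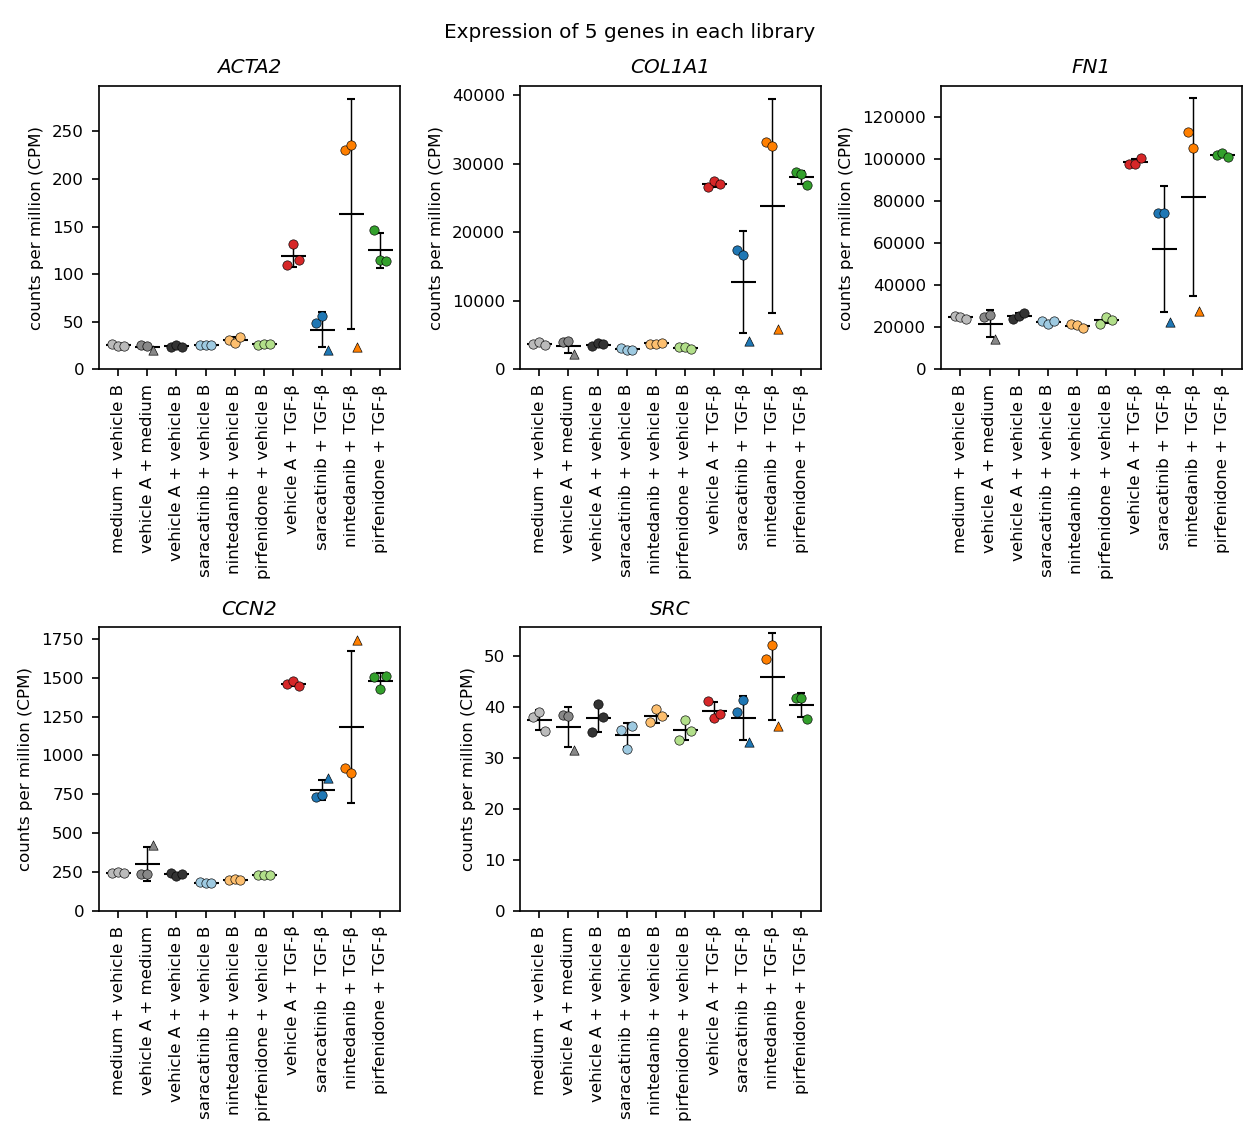
Levels of 5 genes in CPM (axes from 0) in each of the 30 libraries, by treatment; bars are the mean ± SD of 3 libraries, and triangles mark the 3 libraries that stand apart. ACTA2 lies near 24.21 CPM in the unstimulated control and near 118.7 CPM in the TGF-β group, and the triangles with TGF-β lie far below the circles of their groups for ACTA2, COL1A1 and FN1.

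Of 29 collagens and matrix proteins, 27 rose and none fell (28 adjusted over the list alone), with ELN at 6.72, TGFBI at 5.30 and COL11A1 at 3.87 (log2). The list test gave adjusted p = 9.3e-20, and adjusted p = 0.13 with an estimated correlation. SMAD feedback and direct TGF-β targets rose for 15 of 17 (15 adjusted over the list alone), including SERPINE2 (5.45), PMEPA1 (4.93) and IL11 (4.19), with adjusted p = 3.8e-18 for the list. Of 18 contractile genes, 11 rose and 2 fell (13 and 2 adjusted over the list alone), with MYOCD, the smooth-muscle coactivator, at 6.20 and TPM1 at 3.81. NOX4 (6.21) in that list is a peroxide-producing oxidase, not a contractile protein. The contractile list passed at 6.1e-06 but had adjusted p = 0.18 with an estimated correlation. MRTF and SRF targets rose for 12 of 16, and 1 fell (13 and 1 adjusted over the list alone, adjusted p = 5.1e-07), with TUFT1 at 1.87. Matrix proteases and inhibitors rose for 12 of 17, and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 2.7e-07), with ADAM12 at 3.85 and MMP10 at 3.57. Endoplasmic reticulum chaperones rose for all 14 (14 adjusted over the list alone, adjusted p = 2e-16), with DNAJB9 at 1.78 and HYOU1 at 1.72. Of 17 ATF4, serine and one-carbon genes, 16 rose (16 adjusted over the list alone), with CHAC1 at 3.41 and the amino-acid transporter SLC7A5 at 3.23. That list passed at 2.9e-10 and had adjusted p = 0.26 with an estimated correlation.

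Epithelial-mesenchymal transition factors rose for 9 of 15, and 2 fell (9 and 2 adjusted over the list alone, adjusted p = 0.00097), with SNAI1 at 3.23 and the collagen receptor subunit ITGA11 at 3.57. In the WNT pathway 12 of 22 rose and 2 fell (12 and 2 adjusted over the list alone, adjusted p = 0.0073), led by FZD8 (6.08) and by the WNT antagonists NOTUM (3.96) and NKD1 (3.49), which dampen WNT signals. Lipofibroblast and adipogenic genes fell for 6 of 10, and 1 rose (6 and 1 adjusted over the list alone, adjusted p = 0.0095), with FGF10 at −3.43, PPARG at −2.75 and CD36 at −2.30. Of 16 interferon-stimulated genes, 8 fell and none rose (11 adjusted over the list alone), with OAS2 at −2.01 and IFIT3 at −1.43. The interferon list passed at 0.0062 and had adjusted p = 0.39 with an estimated correlation. The SMAD, MRTF, protease, chaperone, EMT, WNT and lipofibroblast lists also passed with an estimated correlation (adjusted p from 8.2e-05 to 0.027). In the model of 27 libraries MRTF (0.074) and WNT (0.14) no longer did, while matrix (4.1e-05) and ATF4 (0.0095) did.

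The remaining 19 lists did not pass as lists. Members went both ways among BMP and ID targets (6 rose, 3 fell of 12, also adjusted over the list alone, adjusted p = 0.21, with HEY1 at 3.08 and BMP4 at −2.04) and YAP and TEAD targets (8 and 3 of 22, 9 and 3 adjusted over the list alone, adjusted p = 0.1). The same held for growth factors (8 and 5 of 20, 8 and 6 adjusted over the list alone, adjusted p = 0.4), with EDN1, the vasoconstrictor endothelin, at 2.81 and HGF at −2.40. For the ERK pathway 6 rose and 3 fell of 18 (7 and 4 adjusted over the list alone, adjusted p = 0.4), and for Src-family kinases and substrates 3 rose and 4 fell of 12 (3 and 4 adjusted over the list alone, adjusted p = 0.94). Medians of the YAP, ERK, growth factor, Src, hypoxia, endothelial and mesothelial lists changed sign with library size as the only scaling, for example from 0.10 to −0.21 for YAP. Means and medians differed in sign for the ERK (−0.02 and 0.06), hypoxia (−0.23 and 0.01) and Src (−0.06 and 0.07) lists. Inflammatory genes had 4 rises and 4 falls of 17 (4 and 5 adjusted over the list alone, adjusted p = 0.94), with IL6 at 2.41 and ICAM1 at −1.98. Hypoxia genes had 4 and 3 of 15 (4 and 3 adjusted over the list alone, adjusted p = 0.79) and NRF2 targets 4 and 4 of 12 (5 and 4 adjusted over the list alone, adjusted p = 0.79). Cholesterol synthesis genes fell for 9 of 19, and 2 rose (9 and 2 adjusted over the list alone, adjusted p = 0.1), with LSS at −1.30, and lysosome genes fell for 4 of 17 (4 adjusted over the list alone, adjusted p = 0.35). AHR targets had 1 rise and 3 falls of 5 (1 and 3 adjusted over the list alone, adjusted p = 0.2) and p53 targets 1 and 1 of 12 (1 and 1 adjusted over the list alone, adjusted p = 0.82), where CDKN2B, a cyclin kinase inhibitor, rose by 2.03. None of 18 DNA replication genes and none of 16 mitosis genes passed (adjusted p = 0.79 for both lists). Of the marker lists, epithelial genes had 2 falls of 4 tested, endothelial 1 rise and 1 fall of 8, leukocyte 1 and 1 of 3, mesothelial 1 rise of 4 and pericyte 2 rises and 3 falls of 7 (p from 0.39 to 0.88). Adjusted over the list alone, these were 1 and 1 for the mesothelial and 2 and 4 for the pericyte list, and the same for the others. The marker levels in the unstimulated control were 17.1 CPM for KRT19, 5.8 for VWF, 0.895 for CD14 and 6.85 for BNC1. CSPG4, a pericyte marker also made by fibroblasts, had 209 CPM.

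Saracatinib with TGF-β was compared with the TGF-β group to ask which TGF-β responses change under this drug. Saracatinib lowered 12 of 14 endoplasmic reticulum chaperones and 7 of 17 SMAD targets, and raised some genes that TGF-β had lowered, such as NR4A3. COMP fell from 21.58 ± 2.16 to 2.241 ± 0.253 CPM (log2 −3.26, SE 0.42, adjusted p = 5.5e-05). CILP, a cartilage matrix protein (ENSG00000138615, chromosome 15, 65194758 to 65211488), fell from 1.858 ± 0.405 to 0.08856 ± 0.0868 CPM (−4.55, SE 1.02, adjusted p = 0.011), and PRG4 from 131.3 ± 12.2 to 13.53 ± 11.3 CPM (−3.29, SE 0.75, adjusted p = 0.011). NR4A3 rose from 0.6247 ± 0.371 to 2.98 ± 0.969 CPM (2.21, SE 0.46, adjusted p = 0.0066). In all, 429 genes rose and 442 fell, 871 of 18950. Leaving out the 3 libraries that stand apart gave 1668 rises and 2201 falls, 3869 in all, and 843 genes were called with the same sign in both models.

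Further named falls under saracatinib were NKD1 (−3.51), NOTUM (−2.44), the growth factor carrier IGFBP3 (−2.30), the parathyroid-related hormone PTHLH (−2.27), SYNDIG1 (−2.25), EGR2 (−1.98) and TSPAN2 (−1.86). Named rises were NPTX1 (3.14), the anticoagulant receptor THBD (2.83), the muscle growth inhibitor MSTN (2.65), PLPPR4 (2.53), the potassium channel KCNJ2 (2.52), LMOD3 (2.39), WNT16 (2.20), HSPB3 (2.09) and the aggrecan protease ADAMTS5 (2.06). Replicate 3 carried much of several changes: without the 3 libraries, CILP was −3.84, WNT16 1.36, NPTX1 1.19, THBD 1.04, ADAMTS5 0.91 and MSTN 0.87, the last of which no longer passed (adjusted p = 0.31). ACTA2 fell by 1.51 on the log2 scale (adjusted p = 0.048, 41.79 ± 18.6 CPM) and CCN2 by 0.91 (adjusted p = 0.006, 776.8 ± 66 CPM). COL1A1 (−1.08, adjusted p = 0.15), FN1 (−0.78, adjusted p = 0.23) and SRC (−0.05, adjusted p = 0.85) did not pass. Without the 3 libraries COL1A1 was −0.66 and FN1 −0.40, and both passed. ACTA2 had 20.7 CPM in replicate 3 and a mean of 52.33 CPM in the rest of its group, against 118.7 CPM in the TGF-β group.

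Among 17 SMAD targets, 7 fell with saracatinib (12 adjusted over the list alone, adjusted p = 1.6e-11), including IL11 (−1.76), SERPINE2 (−1.72) and PMEPA1 (−1.26). In replicate 3, which stands apart, the SMAD list had a median of −0.71 against the rest of its group. Endoplasmic reticulum chaperones fell for 12 of 14 (13 adjusted over the list alone, adjusted p = 5.3e-20), with HYOU1 at −0.70 and HSPA5 at −0.49. Matrix proteins fell for 6 of 29 (25 adjusted over the list alone), with the basement membrane collagen COL4A1 at −1.24 and TNC at −0.56. The matrix list passed at 4.9e-20 and had adjusted p = 0.14 with an estimated correlation. In the model of 27 libraries 27 matrix genes fell, and the estimated correlation gave adjusted p = 5.6e-05. Contractile genes fell for 4 of 18 (9 fell and 1 rose adjusted over the list alone, adjusted p = 4.7e-05), with the oxidase NOX4 at −1.22 and TPM1 at −0.98, and adjusted p = 0.26 with an estimated correlation. ATF4 and one-carbon genes fell for 2 of 17 (9 adjusted over the list alone, adjusted p = 5.7e-10), with PSPH at −0.88, and adjusted p = 0.27 with an estimated correlation. The ATF4 list had a median of −1.44 in replicate 3 against the rest of its group. Leaving out the 3 libraries took the list median from −0.77 to −0.42, with 14 falls and adjusted p = 0.035 with an estimated correlation. Falls also led among MRTF and SRF targets (4 of 16, 7 adjusted over the list alone, adjusted p = 1.9e-06, SRF at −0.44), proteases and inhibitors (4 fell and 1 rose of 17, 7 and 1 adjusted over the list alone, adjusted p = 1.9e-06, TIMP3 at −1.57) and EMT factors (4 of 15, 4 adjusted over the list alone, adjusted p = 0.0015, ZEB1 at −0.52). In the WNT pathway 5 fell and 1 rose of 22 (5 and 2 adjusted over the list alone, adjusted p = 0.017), though the median moved from −0.14 to 0.04 with library size as the only scaling. Interferon-stimulated genes rose for 2 of 16 (6 adjusted over the list alone, adjusted p = 0.015), with OAS2 at 1.61, and adjusted p = 0.39 with an estimated correlation. Cholesterol genes rose for 1 of 19 (adjusted p = 0.01), with adjusted p = 0.44 with an estimated correlation. The SMAD, chaperone, MRTF, protease, EMT and WNT lists held with an estimated correlation (adjusted p from 0.0007 to 0.041), and WNT did not without the 3 libraries (0.19).

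The saracatinib count was 447, 338 and 429 without TGF-β replicate 1, 2 or 3, 457 without saracatinib replicate 3, and 1724 (1551 raised, 173 lowered) with library size as the only scaling, which moved the median of all genes by 0.17. DESeq2 called 1316 genes, and a model of the compared groups alone called 13.

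Nintedanib with TGF-β was compared with the TGF-β group to ask what this drug changes in stimulated cells. Nintedanib lowered 8 of 14 endoplasmic reticulum chaperones and 5 of 18 ERK pathway genes, and raised 3 of 18 contractile genes. DUSP6, the ERK phosphatase that reports ERK activity (ENSG00000139318, chromosome 12, 89347232 to 89353271), fell from 12.84 ± 0.957 to 3.567 ± 2.58 CPM (log2 −1.84, SE 0.27, adjusted p = 0.00046), and was −2.63 at 2.074 CPM without replicate 3, which stands apart. TRIB2, a pseudokinase, fell from 66.09 ± 2.23 to 22.05 ± 1.47 CPM (−1.58, SE 0.18, adjusted p = 1.8e-05). VCAM1, a leukocyte adhesion protein, fell from 14.98 ± 2.02 to 4.09 ± 1.25 CPM (−1.87, SE 0.32, adjusted p = 0.002). PLPPR4 rose from 0.3744 ± 0.192 to 1.701 ± 0.811 CPM (2.16, SE 0.35, adjusted p = 0.00096). Of 18950 genes, 241 rose and 157 fell, 398 in all. The balance was not stable: limma-voom gave 123 raised and 179 lowered, the model with no filter 100 and 120, and library size as the only scaling 349 and 131. Once the 3 libraries that stand apart were left out, 2928 genes rose and 3013 fell, 5941 in all, of which 397 were called with the same sign in both models. There 2387 rose and 3562 fell once a trend with GC content was removed, and 2490 and 3538 for transcript length.

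Named falls under nintedanib also included NKD1 (−1.98), the Notch target HES1 (−1.88), the immediate-early factor EGR1 (−1.43), HECW2-AS1 (−1.43), the ERK-induced factor ETV5 (−1.20), the neuropeptide GAL (−1.17) and the pseudogene RPLP0P2 (−1.14), which can share reads with its parent gene. EPHB6 (2.12), ADAMTS5 (2.11), GALNT15 (2.07), ADAP2 (1.95), PALMD (1.94), LINC00968 (1.83), NR4A3 (1.76) and the cytokine subunit IL12A (1.75) rose. ADAMTS5 was 0.85, IL12A 0.98 and HECW2-AS1 −2.01 without the 3 libraries. None of the 5 genes reported in every group passed: ACTA2 was 0.46 (163.3 ± 121 CPM), COL1A1 −0.18, FN1 −0.26, CCN2 −0.30 (1183 ± 486 CPM) and SRC 0.23, with adjusted p from 0.35 to 0.92. All 5 passed without the 3 libraries, and 2 of them changed sign: ACTA2 was 0.97, COL1A1 0.28, FN1 0.15, CCN2 −0.69 and SRC 0.37.

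Of 18 ERK pathway genes, 5 fell with nintedanib (9 adjusted over the list alone, adjusted p = 5.3e-15), with EPHA2 at −0.63 beside DUSP6, EGR1 and ETV5. In the model of 27 libraries 16 fell, with SPRY4 at −2.35 and ETV4 at −2.13. Endoplasmic reticulum chaperones fell for 8 of 14 (11 adjusted over the list alone, adjusted p = 3.5e-18), with HYOU1 at −0.51 and PDIA4 at −0.46. Proteases and inhibitors had 4 falls and 1 rise of 17 (6 and 1 adjusted over the list alone, adjusted p = 8e-08), with MMP1, the interstitial collagenase, at −1.04 and ADAMTS12 at −0.73. EMT factors fell for 2 of 15 (3 adjusted over the list alone, adjusted p = 0.012), namely CDH11 (−0.61) and ZEB1 (−0.55). These 4 lists held with an estimated correlation (adjusted p from 0.00014 to 0.035), and EMT did not pass without the 3 libraries (0.086). Contractile genes rose for 3 of 18 (6 adjusted over the list alone, adjusted p = 0.021), namely SYNPO2 (1.04), ACTG2 (0.95) and MYL9 (0.36), with adjusted p = 0.55 with an estimated correlation. None of the 29 matrix genes passed singly (0 adjusted over the list alone), and the list passed downward at 1.4e-07, with adjusted p = 0.53 with an estimated correlation. In replicate 3, which stands apart, the matrix list had a median of −1.54 against the rest of its group. In the model of 27 libraries 11 matrix genes rose and 6 fell, and the list did not pass (adjusted p = 0.5). SMAD targets had 0 of 17 (1 fall adjusted over the list alone, adjusted p = 0.00063), with adjusted p = 0.074 with an estimated correlation. Of the 17 ATF4 and one-carbon genes 1 fell (adjusted p = 1.3e-06), with adjusted p = 0.53 with an estimated correlation. This list had a median of −1.76 in replicate 3, and 3 rose and 3 fell without the 3 libraries (adjusted p = 0.79).

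Leaving out a library moved the nintedanib count to 190, 147 and 180 without TGF-β replicate 1, 2 or 3, to 249 without nintedanib replicate 2 and to 1338 without nintedanib replicate 3. DESeq2 called 735 genes, the model with no filter 220, and a model of the compared groups alone 1, TRIB2.

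Pirfenidone with TGF-β was compared with the TGF-β group to ask which TGF-β responses this drug changes. Expression in the pirfenidone libraries lay close to the TGF-β group. ACTA2 had 125.1 ± 18.4 against 118.7 ± 11.5 CPM and CCN2 1481 ± 49.4 against 1461 ± 15.8 CPM (edgeR, SD, n = 3, adjusted p = 1 for each). No gene of 18950 passed in edgeR, with 468 at an unadjusted p under 0.05. DESeq2, limma-voom and limma on the deposited values also called 0, and a model of the pirfenidone and TGF-β groups alone called 28. The count was also 0 without the 3 libraries, with 1217 at an unadjusted p under 0.05. Interferon-stimulated genes were the single list that passed, downward (0 of 16 members passed, list adjusted p = 0.0075), and this list had adjusted p = 0.99 with an estimated correlation. Recovery of simulated changes was measured for saracatinib with TGF-β, where it was 71.6% at 2-fold among genes of at least 1 CPM, and not for pirfenidone.

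Each drug was compared with the unstimulated control to ask what it does without TGF-β. Nintedanib raised 31 genes and lowered 26. CEMIP, which degrades hyaluronan, rose from 109.8 ± 5.45 to 319.5 ± 81.9 CPM (log2 1.54, SE 0.27, adjusted p = 0.0086). SYNPO2, an actin-bundling protein (ENSG00000172403, chromosome 4, 118850688 to 119061247), rose from 79.81 ± 2.29 to 157 ± 1.87 CPM (0.98, SE 0.16, adjusted p = 0.0071). MMP1 (chromosome 11, 102789920 to 102798160) fell from 281.7 ± 6.9 to 90.28 ± 12.2 CPM (−1.64, SE 0.25, adjusted p = 0.0029). PALMD (1.51), PLPPR4 (1.27) and the microtubule protein MAP2 (1.12) were the other named rises. SCG2 (−1.49), WNT7B (−1.36), the amino-acid transporter SLC6A15 (−1.34) and GAL (−0.91) were the other named falls. The count of 57 rests on libraries that are not among the 3 that stand apart. Leaving out the 3 libraries, whose spread enters the model of all 30, gave 1559 rises and 1376 falls, 2935 in sum. The balance there turned to 1549 and 1714 once a trend with GC content was removed, and to 1399 and 1546 for transcript length.

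ERK pathway genes fell for 2 of 18 with nintedanib alone (6 adjusted over the list alone, adjusted p = 1.2e-10), namely ETV5 (−0.80) and SPRED2 (−0.49), with adjusted p = 0.12 with an estimated correlation. Contractile genes rose for 1 of 18, SYNPO2 (2 adjusted over the list alone, adjusted p = 1.1e-07), with adjusted p = 0.18 with an estimated correlation. With the 3 libraries left out, 14 ERK genes fell (adjusted p = 1e-06 with an estimated correlation), 11 contractile genes rose (0.0067), 15 of 18 DNA replication genes fell (0.023) and 16 of 16 mitosis genes fell (0.085). The count of 57 moved to 15, 24 and 8 without nintedanib with vehicle B replicate 1, 2 or 3, and to 32, 9 and 7 without control replicate 1, 2 or 3.

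Saracatinib alone gave 0 genes in edgeR, with 373 at an unadjusted p under 0.05. DESeq2 called 3, limma-voom 0 and limma on the deposited values 6. The 3 of DESeq2, chosen after their values were seen, were the BMP targets ID3 (−1.65) and ID1 (−0.93) and the decoy receptor TNFRSF11B (−0.43). BMP and ID targets as a list were lower (0 of 12 passed, 2 adjusted over the list alone, adjusted p = 3e-07), as were SMAD targets (0 of 17, adjusted p = 4.8e-05), and both lists passed with an estimated correlation (0.0031 and 0.049). When the 3 libraries were left out, 81 genes rose and 135 fell. In that model 17 of 29 matrix genes fell (20 adjusted over the list alone), with ELN at −0.71 and POSTN at −0.62, and so did 5 of 17 SMAD targets (10 adjusted over the list alone), with SERPINE2 at −0.56 and CCN2 at −0.38.

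Pirfenidone alone gave 0 genes in edgeR, with 1110 at an unadjusted p under 0.05, 0 in limma-voom, 3 in limma on the deposited values and 4 in DESeq2. Those 4, chosen after their values were seen, were the ribosomal genes RPL39 (−0.58) and RPS27A (−0.22), the sulfurtransferase TST (−0.45) and the death-domain protein PIDD1 (−0.40). Of the 3 in the deposited values, ST3GAL5-AS1 and SIMALR have symbols. No list passed. In the model of 27 libraries 724 genes rose and 484 fell, 1208 in all, but 167 without pirfenidone with vehicle B replicate 3. The count was 327 (170 and 157) once a trend with GC content was removed, and 995 (552 and 443) for transcript length. From all 30 libraries, leaving out pirfenidone with vehicle B replicate 1 gave 5 genes and leaving out control replicate 1 gave 2, IPMK (0.66) and MINDY2 (0.46). The 5 were EEF1A1P29, EEF1A1P9, AMH, RPL39 (−0.77) and RPS29 (−0.58).

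**Figure D3:**
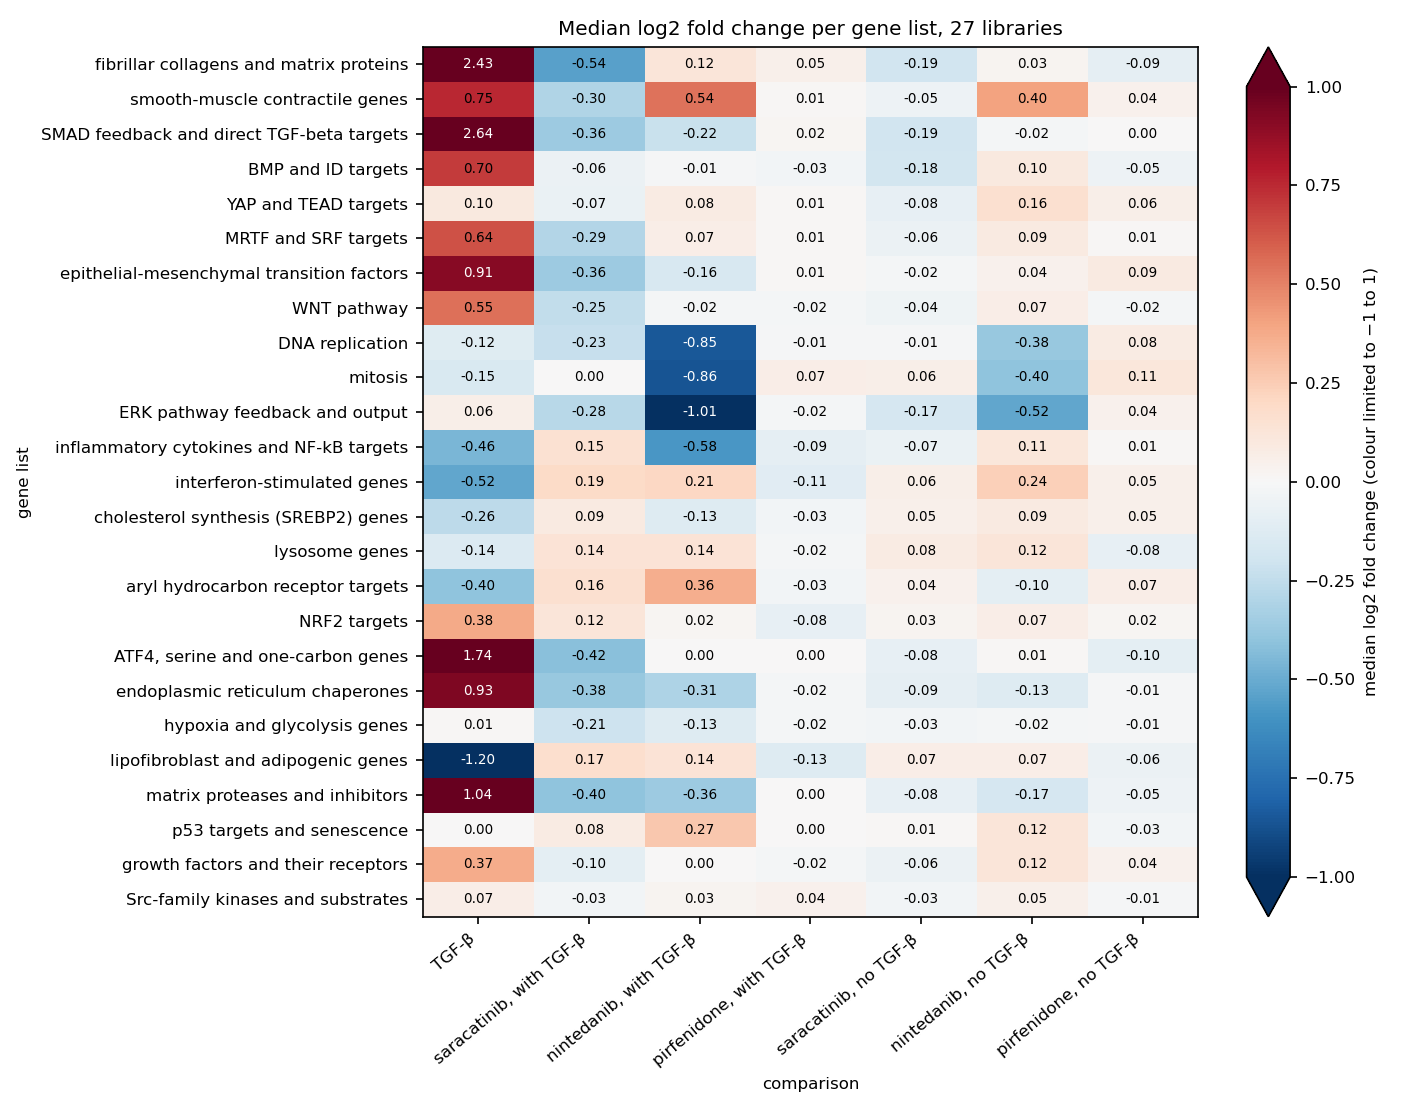
Median log2 fold change of the members of 25 gene lists (all but the 5 cell marker lists) in 7 comparisons, from the 27 libraries without the 3 that stand apart; each cell prints its value and colour stops at −1 and 1. ERK pathway genes lie at −1.01 and contractile genes at 0.54 under nintedanib with TGF-β, and matrix proteins at −0.54 under saracatinib with TGF-β.

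The effect of each drug in stimulated cells was tested against its effect in unstimulated cells. Saracatinib changed 33 genes differently, 19 with a higher and 14 with a lower effect under TGF-β. PLPPR4 (log2 difference 2.47, adjusted p = 0.012), the neuregulin NRG2 (2.45, 0.038), KCNJ2 (2.40, 0.0049), the lymphocyte cytokine IL7 (2.39, 0.038) and CEMIP (2.08, 0.02) had the largest positive differences. Without the 3 libraries these were 1.90 for PLPPR4, 2.28 for NRG2, 2.11 for KCNJ2, 2.51 for IL7 and 1.53 for CEMIP. DRAXIN (−1.92, 0.036), the protease inhibitor TIMP3 (−1.51, 0.0049), WNT9A (−1.23, 0.013), COL4A1 (−1.03, 0.031) and the cyclooxygenase PTGS1 (−0.93, 0.024) had the largest negative ones. With TGF-β, saracatinib took TIMP3 from 763 ± 23.4 to 257.2 ± 45.5 CPM and COL4A1 from 910.9 ± 49 to 384.5 ± 110 CPM. NRG2 went from 0.1403 ± 0.0506 to 0.7947 ± 0.148 CPM and IL7 from 0.2649 ± 0.113 to 0.9729 ± 0.145 CPM. The group means of both genes thus stayed below 1 CPM. Without replicate 3, IL7 with saracatinib and TGF-β had a mean of 1.056 CPM. Of the lists, the difference was negative for endoplasmic reticulum chaperones (1 of 14 passed, HYOU1 at −0.62, 9 adjusted over the list alone, adjusted p = 9.1e-15), SMAD targets (0 of 17, adjusted p = 5.7e-06) and proteases and inhibitors (1 of 17, 3 adjusted over the list alone, adjusted p = 3.9e-05). Matrix genes passed at 3.5e-14 and had adjusted p = 0.31 with an estimated correlation, against 0.0018 without the 3 libraries, where the list median moved from −0.64 to −0.34. The count was 1604 without the 3 libraries and 74 (63 higher, 11 lower) with library size as the only scaling. It was 52 without saracatinib with TGF-β replicate 1 and 20 without its replicate 3. It was 16, 15 and 14 without TGF-β replicate 1, 2 or 3, 16, 12 and 16 without saracatinib with vehicle B replicate 1, 2 or 3, and 11, 20 and 14 without control replicate 1, 2 or 3.

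For nintedanib the test of the difference called 4 genes: the Notch regulator DTX4 (1.32, adjusted p = 0.039), the adhesion receptor ADGRG1 (0.98, 0.039), the ERK-regulated factor ETS2 (0.75, 0.013) and the lipase ABHD2 (−0.48, 0.025). The endoplasmic reticulum chaperones had a negative difference as a list (0 of 14 passed, 6 adjusted over the list alone, adjusted p = 2.2e-09), which held with an estimated correlation (0.04). The count was 2485 (939 higher, 1546 lower) without the 3 libraries. It was 39 without nintedanib with TGF-β replicate 3, 2 without its replicate 1 and 0 without its replicate 2. It was 0, 2 and 0 without TGF-β replicate 1, 2 or 3, 1, 0 and 0 without control replicate 1, 2 or 3, and 0 without any 1 library of nintedanib with vehicle B. Pirfenidone gave 0 in edgeR (822 at an unadjusted p under 0.05), 0 in DESeq2 and limma-voom and 1 in limma on the deposited values, RAB5C-AS1, which was chosen after its value was seen. Its count was 363 without the 3 libraries.

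The drugs were compared with one another in stimulated cells to ask where their transcript profiles differ. With saracatinib 8 of 18 contractile genes were lower and 6 of 18 ERK pathway genes higher than with nintedanib. ACTA2 differed by −1.97 (adjusted p = 0.03), the smooth-muscle myosin MYH11 by −2.06 (0.035) and SYNPO2 by −0.92 (0.005), and the contractile list passed (13 lower adjusted over the list alone, adjusted p = 7.5e-14). DUSP6 differed by 1.95 (adjusted p = 0.00059), EGR1 by 0.96 and ETV5 by 0.80, and the ERK list passed (8 higher and 1 lower adjusted over the list alone, adjusted p = 1.7e-11), with adjusted p = 0.076 with an estimated correlation. COMP (−2.62, adjusted p = 0.0017), TGM1 (−2.34), PTHLH (−1.73), IL11 (−1.63) and CRISPLD2 (−1.44) were lower with saracatinib, and GAPLINC (1.65), OAS2 (1.59), RIPOR3 (1.46) and SLC6A15 (1.26) higher. With the 3 libraries left out, IL11 was −0.88, TGM1 −2.96, OAS2 0.97, GAPLINC 2.41 and DUSP6 2.61. In all 66 genes were higher and 99 lower with saracatinib, 165 in sum, and 4817 without the 3 libraries. The balance turned to 155 higher and 54 lower with library size as the only scaling, which moved the median of all genes by 0.13, and to 103 and 32 in the deposited values. Leaving out nintedanib replicate 1, 2 or 3 gave 50, 35 and 3781, and leaving out saracatinib replicate 1 or 3 gave 88 and 254.

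Against pirfenidone, saracatinib had lower COMP (2.241 ± 0.253 against 24.17 ± 4.77 CPM, log2 −3.43, adjusted p = 2.7e-05), CILP (−4.60), NKD1 (−3.49), PRG4 (−3.35) and NOTUM (−2.42). It had higher MYPN (3.55), LINC01085 (3.33), THBD (3.22), MSTN (3.14) and NPTX1 (3.13). Without the 3 libraries LINC01085 was 2.01, THBD 1.42, NPTX1 1.18 and CILP −3.89, and MYPN (1.38, adjusted p = 0.074) and MSTN (1.35, adjusted p = 0.12) did not pass. Endoplasmic reticulum chaperones were lower for 11 of 14 (13 adjusted over the list alone, adjusted p = 1.8e-18) and SMAD targets for 7 of 17 (9 adjusted over the list alone, adjusted p = 1.9e-10). Interferon-stimulated genes were higher for 5 of 16 (6 adjusted over the list alone, adjusted p = 4.1e-05), with adjusted p = 0.19 with an estimated correlation. The count was 985 (529 higher, 456 lower), 3805 (1764 and 2041) without the 3 libraries, and 317 higher and 516 lower in limma-voom. It was 443, 485 and 481 without pirfenidone replicate 1, 2 or 3, 548 without saracatinib replicate 3, and 2006 (1809 higher, 197 lower) with library size as the only scaling, which moved the median of all genes by 0.18.

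Nintedanib against pirfenidone showed lower TRIB2 (22.05 ± 1.47 against 67.26 ± 1.74 CPM, log2 −1.61, adjusted p = 1.4e-05), DUSP6 (−1.71, adjusted p = 0.00082), NKD1 (−1.96), HES1 (−1.90) and VCAM1 (−1.67). MYPN (3.43), GALNT15 (2.6), ANXA3 (2.49), ADAMTS5 (2.42) and PALMD (2.12) were higher. Leaving out the 3 libraries gave 1.16 for ADAMTS5, 2.69 for MYPN and −2.49 for DUSP6. ERK genes were lower for 6 of 18 (8 adjusted over the list alone, adjusted p = 6.6e-14) and endoplasmic reticulum chaperones for 8 of 14 (11 adjusted over the list alone, adjusted p = 1.1e-17). In all 276 genes were higher and 138 lower, 414 in sum, and 5518 without the 3 libraries. The balance was 139 higher and 153 lower in limma-voom, and 421 and 107 with library size as the only scaling. The count was 189, 190 and 195 without pirfenidone replicate 1, 2 or 3, 272 without nintedanib replicate 2 and 1048 without nintedanib replicate 3.

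How far each drug moved cells along the TGF-β response was summarised by a score over 2348 genes, of which TGF-β raised 893. Libraries of the TGF-β group, scored with themselves held out, had 0.928 ± 0.010 (SD, n = 3). Saracatinib with TGF-β had 0.619 ± 0.114, nintedanib with TGF-β 0.744 ± 0.105 and pirfenidone with TGF-β 0.949 ± 0.005. Each drug group against the TGF-β group gave an exact permutation p of 0.1, the smallest that 3 libraries against 3 can give, so no such comparison could pass 0.05. The scales differ here and below, since drug libraries were scored on all 3 TGF-β libraries and each held-out library on the others. Without TGF-β replicate 1, 2 or 3, pirfenidone had 0.928, 0.932 and 0.928. There saracatinib had 0.606, 0.609 and 0.606, and nintedanib 0.728, 0.733 and 0.728, still below 0.928. The excess of pirfenidone over the TGF-β group is therefore not read as an effect, nor is its p. Without the 3 libraries the scores were 0.681, 0.799 and 0.942 against 0.915. Among genes that TGF-β lowered, the score was 0.89 in the TGF-β group, 0.616 ± 0.023 with saracatinib and 0.691 ± 0.003 with nintedanib. Among genes that TGF-β raised, nintedanib had 0.818 ± 0.246 with its replicate 3 and 0.968 ± 0.022 in the model without the 3 libraries, where the TGF-β group had 0.965. The slope of the TGF-β response with a drug on the response without it, over groups that share no library, was 0.639 (SE 0.086) with saracatinib, 0.765 (SE 0.085) with nintedanib and 0.932 (SE 0.011) with pirfenidone. The genes were chosen by the response without drug, which by itself can pull these slopes below 1, and no slope without a drug effect was computed. The slopes are therefore no measure of how far a drug reduced the response, and 0.932 is not read as an effect of pirfenidone.

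**Figure D4:**
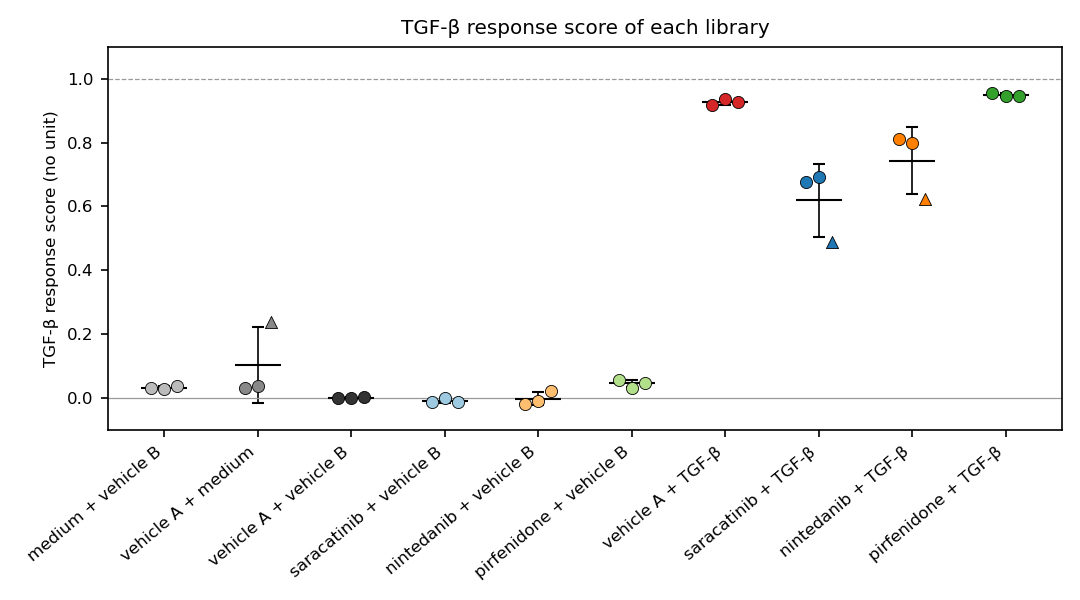
TGF-β response score (no unit) of each of the 30 libraries by treatment; 0 is the mean of the unstimulated control and 1 that of the TGF-β group before libraries were held out, bars are mean ± SD of 3 libraries, and triangles mark the 3 libraries that stand apart. Saracatinib with TGF-β lies at 0.619 ± 0.114, below nintedanib at 0.744 ± 0.105 and pirfenidone at 0.949 ± 0.005.

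Of the 2348 genes, saracatinib opposed the TGF-β change in 456 and enhanced it in 0. Of these, 179 rose with TGF-β and fell with the drug, and 277 did the reverse. Nintedanib opposed 154 (45 and 109) and enhanced 4, and pirfenidone had 0 of either kind. Both contrasts use the same TGF-β libraries, which by itself gives a negative relation, so the counts were set against 20 simulated data sets without a drug effect, where the mean was 2.6 and the highest 9. Simulated libraries were drawn independently of one another. The simulated values here and below thus cover the shared control, and not the shift that replicate 3 of both drug groups shares. The correlation across genes was −0.68 for saracatinib against −0.22 in simulation, with genes not being independent replicates. Saracatinib and nintedanib shared 118 genes raised and 81 lowered in stimulated cells, against 5.5 and 3.7 for independent lists and at most 4 and 2 in simulation, and 1 gene went opposite ways. The correlation of their effects across genes was 0.65, against 0.52 in simulation. In the model without the 3 libraries, over 2725 genes, saracatinib opposed 1112 and enhanced 8, and nintedanib opposed 805 and enhanced 246. There both drugs raised 868 genes and lowered 1021, against 253.2 and 343.8 for independent lists, and 346 went opposite ways, with a correlation across genes of 0.46 against 0.38 in simulation. In the single-library tests the genes opposed by saracatinib numbered 260, 211 and 237 without TGF-β replicate 1, 2 or 3 and 232 without saracatinib replicate 3. For nintedanib it was 91, 65 and 81 without TGF-β replicate 1, 2 or 3 and 279 without nintedanib replicate 3.

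The vehicles were compared with medium to ask whether they act on these transcripts. Over the 6 unstimulated groups, mean ACTA2 lay between 23.41 and 30.75 CPM, COL1A1 between 2964 and 3782 CPM, FN1 between 20720 and 25360 CPM and SRC between 34.51 and 38.27 CPM. CCN2 lay between 180.2 and 300.5 CPM and was highest in vehicle A with medium, which holds 1 of the 3 libraries that stand apart. Vehicle B changed 0 genes in edgeR (736 at an unadjusted p under 0.05), DESeq2 and limma-voom, and 4 in limma on the deposited values. Vehicle A changed 0 in edgeR (300 at an unadjusted p under 0.05), DESeq2 and limma-voom, and 4 in limma on the deposited values. Those with a symbol, chosen after their values were seen, were the noncoding genes SMCR2 and SIMALR for vehicle B and NDNF-AS1 and RNU6-878P for vehicle A. Without the 3 libraries vehicle B had 0 and vehicle A 3, also chosen after their values were seen: EHD3 (−0.21), TM4SF1 (−0.21) and the methyltransferase INMT (−0.32). DNA replication (adjusted p = 0.0018), mitosis (0.0081), YAP (0.011) and MRTF (0.046) lists passed downward and the p53 list upward (0.011) for vehicle B, with 0 members passing, and none held with an estimated correlation (adjusted p = 0.72 for 4 of them and 0.75 for mitosis). The medium group holds vehicle A with medium replicate 3, which stands apart in the reverse direction, with a median of 1.52 for DNA replication, 1.26 for mitosis, 0.77 for YAP and −0.82 for p53. None of the 5 lists passed without it and the 2 others (adjusted p from 0.18 to 0.91).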

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

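The tests in this part were planned, and the models without the 3 libraries that stand apart were added after the results had been seen. The results below drew attention because a drug's effect with TGF-β differed, by a test of the difference itself, from its effect without TGF-β. For saracatinib 33 genes differed. The differences (log2) were 2.47 for PLPPR4, 2.45 for NRG2, 2.40 for KCNJ2, 2.39 for IL7 and 2.08 for CEMIP. Without the 3 libraries, PLPPR4 had 1.90, NRG2 2.28, KCNJ2 2.11, IL7 2.51 and CEMIP 1.53. With all libraries, other differences were negative. They were −1.92 for DRAXIN, −1.51 for TIMP3, −1.23 for WNT9A, −1.03 for COL4A1 and −0.93 for PTGS1. For nintedanib 4 genes differed: DTX4 by 1.32, ADGRG1 by 0.98, ETS2 by 0.75 and ABHD2 by −0.48.

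Other splits of the same libraries were counted for each comparison. For the saracatinib difference, 6 of 30 splits drawn from 200 gave at least 33 genes and the highest other split gave 262, so chance cannot be excluded for that count. A split with several times the real count points to a structure of the samples, whose source was not tested; 1 of the 3 libraries that stand apart is among the libraries split. For the nintedanib difference, 1 of 30 splits drawn from 200, the real one, gave 4 genes or more and the highest other gave 1. Other splits mix treatments within a group, and the count ranged from 0 to 39 when 1 library was left out. Chance is therefore not excluded for this count either. For the pirfenidone difference all 30 splits reached the real count of 0. Splits of 3 libraries against 3 are 10 in number, too few for a share under 0.05. The real counts and the highest of the other splits were 6170 and 0 for TGF-β, 871 and 1 for saracatinib with TGF-β, 398 and 7 for nintedanib with TGF-β, and 57 and 0 for nintedanib alone. They were 985 and 0 for saracatinib against pirfenidone and 414 and 2 for nintedanib against pirfenidone. For saracatinib against nintedanib 5 of 10 splits reached the real count of 165 and the highest other gave 6691. Each of these groups holds 1 library that stands apart. The splits with 2122, 2786, 6463 and 6691 genes are those that put both of these libraries on the same side. No other split besides the real one gave more than 9, so the high counts go with the placing of these libraries. Pirfenidone with TGF-β, saracatinib alone, pirfenidone alone and both vehicles had 0 in the real split and 0 in the highest other.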

How the results depend on the processing

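The models without the 3 libraries that stand apart, with a term for them, and the leave-one-out slopes were chosen after the data had been seen. Counts within 1.5 times the reported one are not repeated, the cause of a changed count was not tested except where fewer genes, libraries or a stricter threshold explain it, and no paired analysis was made because nothing in the labels ties a replicate number to a batch or culture shared between groups. Without the 3 libraries TGF-β had 9557, saracatinib with TGF-β 3869, nintedanib with TGF-β 5941, saracatinib alone 216, nintedanib alone 2935, pirfenidone alone 1208, the differences with TGF-β 1604 (saracatinib), 2485 (nintedanib) and 363 (pirfenidone), saracatinib against nintedanib 4817, saracatinib against pirfenidone 3805, nintedanib against pirfenidone 5518 and vehicle A 3. With a term for them the counts were 3253 and 4581 for saracatinib and nintedanib with TGF-β, 16, 1513 and 31 for saracatinib, nintedanib and pirfenidone alone, 801 and 477 for the saracatinib and nintedanib differences, and 2738, 3119 and 4187 for the drug pairs. Removing these libraries lowered the dispersion from 0.0351 to 0.00303. With a 2-fold minimum the counts were 2348 for TGF-β, 215 and 84 for saracatinib and nintedanib with TGF-β, 8 for nintedanib alone, 17 and 1 for the saracatinib and nintedanib differences, and 32, 262 and 102 for the drug pairs. With library size as the only scaling they were 1724 for saracatinib with TGF-β, 74 and 1 for the differences and 2006 for saracatinib against pirfenidone. DESeq2 gave 1316 and 735 for saracatinib and nintedanib with TGF-β, 3, 146 and 4 for saracatinib, nintedanib and pirfenidone alone, 140 and 35 for the differences, 331 for saracatinib against nintedanib and 696 for nintedanib against pirfenidone. Limma on the deposited values gave 6 for saracatinib alone, 3 for pirfenidone alone, 19, 2 and 1 for the saracatinib, nintedanib and pirfenidone differences and 4 for each vehicle. Models of the compared groups alone gave 13, 1 and 28 for the drugs with TGF-β, 145, 2455 and 249 for the drugs alone, 52, 11 and 297 for the differences, and 0, 28 and 1 for the drug pairs. With no filter beyond 1 count nintedanib with TGF-β had 220, saracatinib alone 1, nintedanib alone 30 and nintedanib against pirfenidone 253. Vehicle A with medium as the control gave 254 for nintedanib alone and 3 for pirfenidone alone, and the mean of the 3 unstimulated groups gave 1, 346 and 2 for saracatinib, nintedanib and pirfenidone alone. Genes opposed by saracatinib numbered 1112 without the 3 libraries, 1075 with the term and 838 with no fold minimum, and genes opposed by nintedanib 805, 739 and 323, with 270 by DESeq2. The pirfenidone score moved by more than its SD to 0.935 with a prior count of 0.5, 0.956 with genes chosen by adjusted p alone, 1.012 with genes of at least 10 CPM, 0.96 with vehicle A in medium as the zero, and 0.942 without the 3 libraries. The gene lists had 106 calls with the preset correlation and 39 with the estimated one. Calls of SRC for TGF-β were −0.26 (adjusted p = 0.018) with library size alone and −0.26 (0.043) in the deposited values, which carry no other scaling. For nintedanib with TGF-β, COL1A1 was 0.28 and FN1 0.15 without the 3 libraries. Each library of the groups compared, and no other, was left out in turn. This gave 5110 to 5284 for TGF-β, 338 to 1015 for saracatinib with TGF-β, 147 to 1338 for nintedanib with TGF-β, 7 to 32 for nintedanib alone, 0 to 5 for pirfenidone alone, 11 to 52 and 0 to 39 for the saracatinib and nintedanib differences, 35 to 3781 for saracatinib against nintedanib, 443 to 1125 for saracatinib against pirfenidone and 189 to 1048 for nintedanib against pirfenidone. It gave 0 to 0 for pirfenidone with TGF-β, saracatinib alone, the pirfenidone difference and both vehicles. Among these, only the vehicle B comparison holds a library that stands apart, so in the others the 3 libraries always stayed in the model. Genes opposed ranged from 211 to 496 (saracatinib), 65 to 279 (nintedanib) and 0 to 0 (pirfenidone), scores from 0.582 to 0.684, 0.711 to 0.804 and 0.928 to 0.96, and slopes from 0.592 to 0.724, 0.719 to 0.85 and 0.919 to 0.937. Of 430 pairs of a named gene and a comparison, the sign and side of the threshold held in 427 with DESeq2, 422 with RLE, 403 with no filter, 392 with library size, 362 with limma-voom, 337 in the deposited values and 409 without the 3 libraries, in 180 of 427 with models of the compared groups alone, and in 1954 of 2682 with 1 library left out. Depth limits genes near the floor of 3 counts per group, for which bounds or counting intervals are given.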

Other observations

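The tests of the 3 libraries that stand apart and of the saracatinib score were chosen after the results had been seen, as was the division of the marker test and its lower bound, while the tests of the contractile genes and of pirfenidone were written before their values were computed. Without the 3 libraries, cell cycle genes were lower with nintedanib and TGF-β than with TGF-β: 18 of 18 DNA replication genes fell (adjusted p = 0.0088 for the list with an estimated correlation), with the cyclin CCNE2 at −2.52, CDC45 at −1.82 and RRM2 at −1.58 (log2). All 16 mitosis genes fell (0.028 for the list), with AURKB at −1.46 and CDK1 at −1.35. Inflammatory genes fell for 7 of 17 (0.028), including the chemokines CXCL8 (−1.64) and CCL2 (−1.50). Saracatinib in the same model lowered 6 DNA replication genes and raised 2 mitosis genes, and in the ERK pathway 11 of 18 genes fell and 1 rose (0.0043). Nintedanib in this model rests on 2 libraries with TGF-β. From all 30 libraries no DNA replication or mitosis gene passed for nintedanib with TGF-β, neither list did (adjusted p = 0.44 and 0.28), and their medians were 0.37 and 0.20, upward.

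The 3 libraries that stand apart shared a set of genes whatever their treatment. Of 18950 genes, 1259 deviated by at least 1 (log2) from the rest of the group in the same direction in all 3, 662 higher and 597 lower. DNA replication genes were higher in all 3 for 17 of 18, mitosis genes for 13 of 16 and inflammatory genes for 7 of 17, and p53 targets were lower for 5 of 12. Among genes singled out after their values were seen, ESM1, the secreted proteoglycan endocan, had 83.2, 134 and 271 CPM against 4.8, 8.51 and 2.76 CPM in the rest of their groups. HAS2, the hyaluronan synthase, had 588, 662 and 506 against 88.6, 159 and 88.4 CPM. STC1, a secreted glycoprotein, had 225, 243 and 179 against 51.5, 17.1 and 4.15 CPM, and FOSL1, an AP-1 factor, 206, 145 and 84.1 against 40.6, 17 and 6.55 CPM. ITGA11, a collagen receptor subunit, had 1.74, 2.09 and 2.4 against 6.19, 51.3 and 110 CPM, and MFAP4, a microfibril protein, 14.4, 16.2 and 21.9 against 90.4, 318 and 594 CPM.

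For these 3 libraries the tables argue against lower depth, since the lowest total of the 3 was 46.1 M against a median of 43 M in the other 27. They also argue against RNA from endothelial or blood cells as the whole cause. The 597 genes lowered at least 2-fold in all 3 would need no less RNA from other cells than from the fibroblasts, yet the highest tested marker of these cells had 3.76 CPM in the 3 libraries. This covers the 8 endothelial and 3 leukocyte markers that were tested. ESM1, whose full name refers to endothelial cells, is not among them and was higher in the 3 libraries. RNA from mesothelial or pericyte cells stays open: the lowest median deviation was 0 or less, but over 4 and 7 tested markers, the most abundant at 14.6 and 176 CPM. RNA from epithelial cells stays open too, with a lowest median deviation of 0.49 over 4 tested markers, the most abundant of which reached 42.6 CPM in these libraries. One shift common to the 3 libraries may account for part of the pattern, with a lowest correlation of their deviations across genes of 0.563, which lies between the bounds set. The libraries themselves correlated with one another at 0.99 to 0.997, above their means of 0.981, 0.978 and 0.969 with their own groups. Deviations are taken from groups with and without TGF-β, so equal levels in the 3 libraries can give unequal deviations. The labels name nothing that these libraries share, and no biological explanation was tested.

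Contractile genes were higher with nintedanib and TGF-β once the 3 libraries were left out, with 13 of 18 raised and 1 lowered and a median of 0.54. The lowest median was 0.52 over 3 other scalings, 0.42 once a trend with GC content was removed and 0.51 once a trend with transcript length was removed, so the tables argue against each of these as the whole cause. In all 30 libraries 3 of 18 rose, and nintedanib replicate 3, which stands apart, had lower ACTA2 than its group. A rise of contractile genes under nintedanib is a hypothesis, which may be tested with more libraries.

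For pirfenidone alone, 1208 genes were called without the 3 libraries. Removal of a trend with transcript length left 995, which argues against length as the whole cause. Removal of a trend with GC content left 327, of which 215 were among the 1208, so GC content may account for many of the calls. Median GC content was 38.8% in the 724 raised genes, 58.8% in the 484 lowered genes and 48% in the genes not called. A single library stays open: the count was 167 without pirfenidone with vehicle B replicate 3, and 1082 and 1123 without replicate 1 or 2.

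Whether saracatinib without added TGF-β lowers the TGF-β response score was tested after the values were seen. Its 3 libraries had −0.009 ± 0.007 against 0.066 ± 0.085 in the 6 libraries of vehicle A in medium and of medium with vehicle B, an exact permutation p of 0.15, two-sided. Without the library that stands apart the 5 others had 0.032 ± 0.004 and the exact p was 0.018. The matched control, which sets the 0 of the score, had 0 ± 0.002 and nintedanib alone −0.004 ± 0.021. Over the genes that TGF-β raised, saracatinib alone had −0.023 ± 0.008, the matched control 0 ± 0.006 and nintedanib alone 0.045 ± 0.006. Over the genes that TGF-β lowered these were 0.002 ± 0.011, 0 ± 0.002 and −0.038 ± 0.034. Whether a lowering is particular to saracatinib stays open, because the parts of the score were compared after their values were seen and not tested.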
